A study of Arabidopsis thaliana with 12 samples.

How the data were processed

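Gene expression was measured by array in 12 samples of total RNA from wild-type plants, 6 at normal CO2 and 6 after 48 h at 0.003% CO2, grouped by the sample titles, which also gave the replicate numbers 1 to 6. The table held deposited intensity values on a linear scale, with array means near 1, values of 0 and an upper bound of 100. The scanner, background correction and scaling that the authors used are not given in the sources used here, so it is unknown over which probes the arrays were scaled. Of all values 5.55% were 0, 152 ± 18.2 per array at normal and 230 ± 49.6 at low CO2 (SD, n = 6 each), and 14 values of 4 probes lay at the upper bound.

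Gene names came from a platform annotation that lists 1562 of the 3439 probes, 692 with 1 gene. Of those 692, 690 were matched to the reference TAIR10.1, used for names only, and the others kept the annotation's name. A probe that is not listed is unnamed here, and whether it stands for a gene or a control spot could not be told. The plan fixed beforehand left out control spots and rows with no gene identifier. In a departure from it, every row entered the tests. The array's genome build is not given in the sources used here, and no coordinates are printed. For a gene with several probes the brightest stood for it in gene lists.

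Values of 0 were set to the smallest positive value of their array and log2 taken. As array medians differed by more than 5%, arrays were quantile normalized. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 6 against 6, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with 5 or more measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, adjusted over 1 list fixed beforehand and over 3 lists added later. Apart from the keeping of unlisted probes, the test, lists and rules for naming genes were fixed before the data were examined. Named were the 10 largest rises and 10 largest falls among genes past the threshold and above the 25th percentile of mean signal, up to 2 members per direction of each list by smallest p, and a set of fixed genes, of which PRK was measured.

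Deviations from the group mean were correlated between samples. A rule fixed beforehand called for averaging adjacent samples where every mutual best pair reached 0.3, and 1 of the 6 pairs did, so 6 samples per group were kept. Within its group, the mutual best partner was nevertheless the adjacent number for all 12 samples. Samples with the same number in the 2 groups correlated at 0.128 to 0.214, every pair above 0.1, so that the numbers, taken from the titles, paired the samples across groups.

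The procedure was tested on simulated data with the means and spreads of the 3439 probes, of which 200 were changed. With independent noise, the fit of 6 against 6 recovered 8.96%, 41.8% and 66.7% of changes of 0.5, 1 and 2 on the log2 scale, and 2.50% of its calls were false. When noise was shared within pairs at a correlation of 0.567, the value estimated in the data, 32.1% of its calls were false, against 4.55% with pair averages and 2.94% with pairs as a random block. With that noise, pair averages recovered 31.8% of changes of 2 on the log2 scale. The false share depends on how many probes truly change. As 200 were changed here and the data gave 1457 calls, these shares do not carry over to the data. Each kind of noise was drawn a single time, and the 4.55% was 1 of 22 calls.

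Alternatives fixed beforehand were other scalings (none, median, 75th percentile, cyclic loess), a replicate block, pair averages, pairs as a random block, a filter on dim probes, a pseudocount of 0.0493 (the 10th percentile of all values), a prior variance with trend and robust estimation, a 1.5-fold minimum and each replicate left out. Added after seeing the data were pair averages with a replicate block, each pair of numbers left out, probes with a 0 left out, and a correction for the place of a probe in a repeat along the probe numbers. The repeat was taken as 288 numbers, a 16th of the numbering, in 48 bins of 6 numbers, and fold changes were held within 3 on the log2 scale to measure it.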

Results

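The data set concerned wild-type Arabidopsis thaliana plants of the Columbia 0 ecotype. Gene expression after 48 h in air holding 0.003% CO2 by volume was compared with that at normal CO2. The sample titles give day 0 for all normal CO2 samples and day 2 for all low CO2 samples. Changes with CO2 thus cannot be told apart from changes over the time between the groups. Total RNA was measured on an array of 3439 probes in 12 samples, 6 per group. The labels do not say whether the 6 samples of a group came from separate plants, so the p-values measured only the spread between these samples, which may be technical. Of the probes, 692 were listed with 1 gene, 870 with several genes and 1877 were unnamed here, and genes are named only from the first kind. Deposited intensities had an array median of 0.519 ± 0.0404 at normal CO2 and 0.359 ± 0.0111 at low CO2 (SD, n = 6 each), while the array means were 1.07 ± 0.0175 and 1.02 ± 0.0155. The 35 brightest probes held 20.2% ± 0.836 of the signal at normal CO2 and 29.7% ± 0.919 at low CO2. Fold changes below are relative to the distribution of all probes on an array, which were set equal between arrays, and precision is limited by the number of arrays.

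Which transcripts changed after 48 h at low CO2 was the question of the comparison. The named gene with the largest rise was AT4G35660, whose deposited intensity went from 0.555 ± 0.157 to 11.9 ± 1.42 (SD, n = 6 each), a log2 fold change of 4.69 ± 0.21 (SE, limma adjusted p = 6.95e-08). AT5G39980 and AT3G13150, both encoding pentatricopeptide repeat proteins, a family that binds organelle RNA, rose by 3.35 ± 0.46 and 2.96 ± 0.32 on the log2 scale. AT5G55580, encoding the mTERF9 protein, rose by 2.72 ± 0.36, and AT3G23940, encoding dihydroxy-acid dehydratase of branched-chain amino acid synthesis, rose by 2.86 ± 0.67, or by 1.90 on the deposited scale. AT2G32040, encoding a folate transporter, and AT5G40470 had falls of the same size, with log2 fold changes of -2.81 ± 0.16 (limma adjusted p = 4.92e-07) and -2.81 ± 0.22 (adjusted p = 4.13e-06).

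The other genes among the 10 largest rises were AT4G39760 at 3.28, AT1G74070 at 3.09, AT5G04600 at 2.70, AT1G35510 at 2.54 and AT1G72020 at 2.46 on the log2 scale. Among the other genes with the 10 largest falls, AT1G79080, another pentatricopeptide repeat gene, changed by -2.53 and AT1G78790, the gene of the histone-fold protein MHF2, by -2.22, or by -1.64 without low CO2 replicate 6. AT3G11150 changed by -2.20, AT2G30320, encoding a pseudouridine synthase, by -2.18, AT4G33500, encoding a type of protein phosphatase known as PP2C, by -2.18 and SWAP70 by -2.03. AT1G04420, encoding an aldo-keto reductase, changed by -1.88 and GH9B11, a glycosyl hydrolase gene, by -1.82. The value of GH9B11 in low CO2 replicate 4 was 0.0030, near 0. With 1 sample left out its change ran from -2.04 to -1.39. On the deposited scale AT5G04600 was at 1.61, AT1G72020 at 1.81, AT1G79080 at -3.18, AT1G78790 at -2.87, SWAP70 at -2.64 and GH9B11 at -2.93. With the pseudocount AT5G04600 was at 1.83, AT3G23940 at 2.04 and AT1G78790 at -1.63, all past the threshold. The deposited values of the groups did not overlap for 19 of these 20 genes, the exception being AT1G72020. Chance separates 0.216% of probes if the 12 samples are independent and 10% if each adjacent pair counts once, and these genes were picked for large changes. Separation was common in these data. Of all 3439 probes, 1188 (34.5%) had no overlap, 972 of them among the 1457 that changed by limma. Deposited values also carry the lower array medians at low CO2. Among unnamed probes, probe 4444 rose by 5.33 and probe 454 by 4.96, while probe 1424 changed by -3.29 and probe 4371 by -3.96 ± 1.38 (SE, adjusted p = 0.0378). Probe 4371 had a value of 0 in 1 low CO2 sample. It did not pass with adjacent samples averaged (adjusted p = 0.105) or with adjacent pairs as a random block (0.194). With the place of the probe in the numbering taken off it was at -3.39 and did not pass either (adjusted p = 0.0843).

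**Figure D1:**
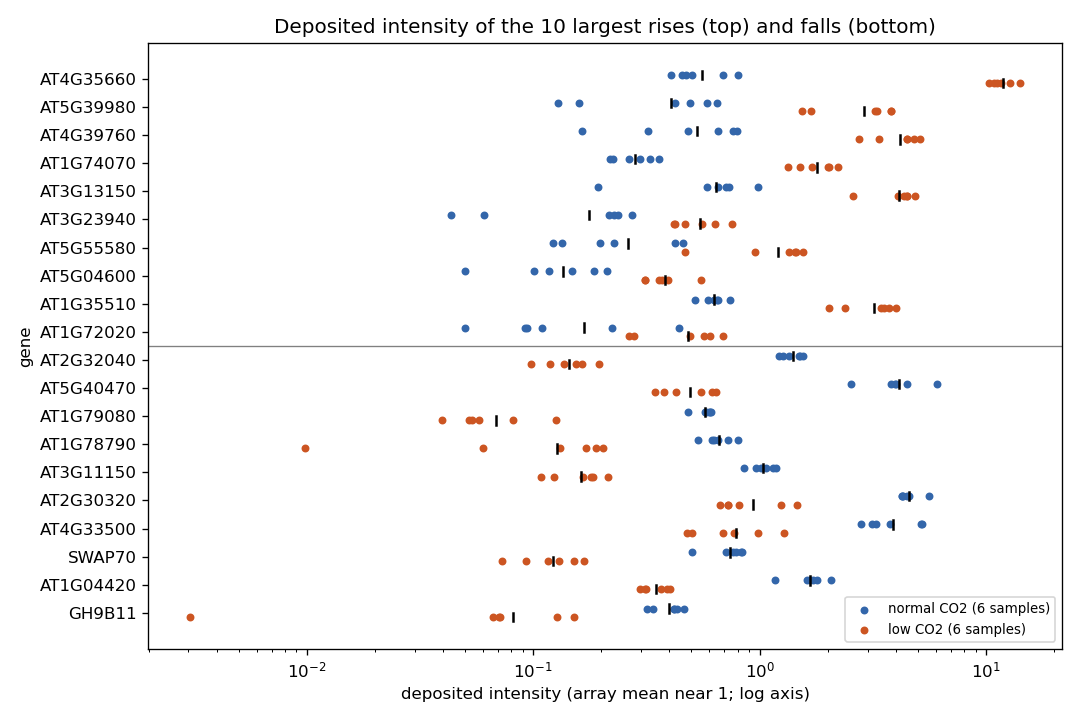
Deposited intensity (horizontal log axis, array mean near 1) of the 10 named genes with the largest rises and the 10 with the largest falls; points are samples, 6 at normal CO2 in blue and 6 at low CO2 in orange, and black bars are group means. The values of AT4G35660 lie between 0.405 and 0.804 at normal CO2 and between 10.4 and 14.2 at low CO2.

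In all, 1457 of the 3439 probes (42.4%) changed by limma with Benjamini-Hochberg adjusted p under 0.05, 649 of them higher and 808 lower at low CO2. Of these, 856 changed at least 2-fold, 420 upward and 436 downward. Among probes of 1 gene, 280 of 692 changed, 129 upward and 151 downward. Of the probes not listed in the annotation, 788 of 1877 changed, 338 upward and 450 downward. On the deposited scale 1675 probes changed, 373 of them higher and 1302 lower, and the median log2 fold change of all probes was -0.60 there against -0.05 after quantile normalization.

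Within each group every sample resembled most the one with the adjacent number (1 and 2, 3 and 4, 5 and 6). The correlation within such pairs was estimated at 0.567, limma's consensus over the probes. Deviations from the group mean, correlated over all probes, gave lower values. Their mean within pairs was 0.179 at normal and 0.0207 at low CO2, against -0.284 and -0.249 between pairs. The 6 samples of a group were thus not independent, and on that account the p-values and SEs above are likely too small. Same-numbered samples of the 2 groups also deviated together, at correlations of 0.128 to 0.214. The fit without a block ignores this pairing, which by itself can make p-values too large. With a replicate block 1578 probes changed. With the pairs averaged, 618 probes changed, 606 of them shared with the 1457, and with pairs as a random block 1006 changed. Pair averages with a replicate block, a setting added after seeing the data, gave 375. Of the 20 genes above, 18 passed on pair averages, and AT3G23940 (adjusted p = 0.0950) and AT1G78790 (adjusted p = 0.105) did not, the latter also not with pairs as a random block (0.0519). GH9B11 passed on pair averages (adjusted p = 0.0429) but not with pairs as a random block (0.0811). The SEs of fold changes printed above and below come from the fit of 6 against 6. On pair averages the SE was 0.32 instead of 0.21 for AT4G35660 and 0.66 instead of 0.46 for AT5G39980. For AT3G13150 it was 0.31 instead of 0.32.

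Fold changes also followed the probe number. Along the numbers, which run up to 4607, they repeated at about 288 numbers, a length set as a 16th of the numbering. Fold changes 288 numbers apart correlated at 0.284. Among lags over 11 the highest correlation was 0.299, at 287, and at a lag of 1 it was 0.262. The place in this repeat, in 48 bins, held 24.4% of the variance of the fold changes of the 2579 brighter probes. All 10 of the largest rises lay in bins with a median above 0 and 9 of the 10 largest falls in the other bins. With each sample's median deviation per bin taken off, a step chosen after seeing the data, 1291 probes changed, 899 of them shared with the 1457 and in the same direction, and with pair averages as well 454 changed. AT4G35660 then changed by 4.05, AT4G39760 by 2.53, AT5G40470 by -3.37, AT2G32040 by -2.04, AT2G30320 by -1.46 and AT1G04420 by -1.28, all past the threshold. AT5G04600 (1.61, adjusted p = 0.0653) and GH9B11 (-1.26, adjusted p = 0.0661) no longer passed. Of all 41 named genes, 32 passed with the place taken off and 22 with pair averages as well.

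**Figure D2:**
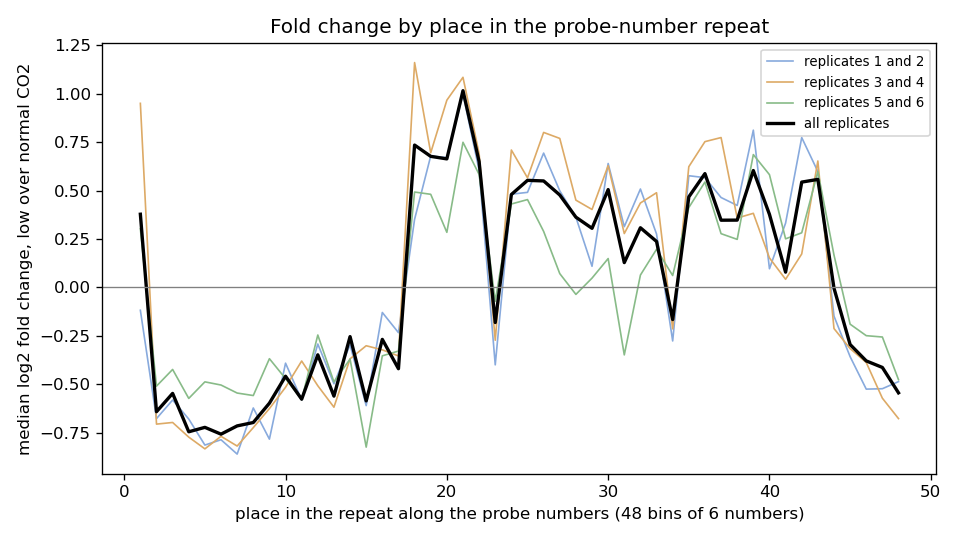
Median log2 fold change, low over normal CO2 (vertical axis), of the brighter probes in each of 48 bins of the repeat along the probe numbers (horizontal axis); the black line is all replicates and the coloured lines are the pairs of replicates. The medians of the bins run from -0.76 to 1.01, and the profiles of the pairs correlate across bins at 0.856 to 0.905.

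The gene groups were those of plastid function, fixed before the data were examined, and 13 of the 27 lists had a measured member. Both measured genes of the Calvin-Benson cycle, which fixes CO2, fell. PRK, encoding phosphoribulokinase, changed by -0.73 ± 0.17 (SE, limma adjusted p = 0.00451) and SBPASE, encoding sedoheptulose-bisphosphatase, by -0.68 ± 0.17 (adjusted p = 0.00626). Neither passed on pair averages (adjusted p = 0.110 and 0.0996), and with the place in the repeat taken off PRK was at -0.39 (adjusted p = 0.0275) and SBPASE at -0.13 (adjusted p = 0.485). On the deposited scale PRK was at -1.02 and SBPASE at -1.20 (adjusted p = 0.000398 and 0.000241). Both also passed when adjusted over the list alone.

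Of 3 measured photosystem II subunit genes, PSBW rose by 0.97 ± 0.19 (adjusted p = 0.00178) and PSBY by 0.46 ± 0.17 (adjusted p = 0.0474), and PSB27 was at 0.41 ± 0.56 (adjusted p = 0.590). Neither rise passed on pair averages (adjusted p = 0.0775 and 0.253), and PSBY did not pass on the deposited scale (0.21, adjusted p = 0.386) or in 9 of the 12 fits that left out 1 sample. With the place taken off PSBW was at 1.52 and PSBY at 0.99, and both then passed on pair averages too (adjusted p = 0.0232 and 0.0175). The light-harvesting gene LHB1B2, the only measured antenna gene, fell with a log2 fold change of -0.97 ± 0.19 (adjusted p = 0.00178; 0.0802 on pair averages) and was at -0.41 with the place taken off (adjusted p = 0.0373), and its close paralogs may share its probe. The photosystem I subunit gene PSAN was at -0.19 ± 0.32 (adjusted p = 0.662). Counts adjusted over the list alone were the same in these 3 lists.

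The single measured photorespiration gene, LrgB, the plastid glycolate and glycerate transporter, rose by 1.57 ± 0.49 (adjusted p = 0.0231, 0.0413 on pair averages and 0.203 with pairs as a random block). It was, however, dim, at 0.141 ± 0.0700 and 0.200 ± 0.0573. It did not pass on the deposited scale (0.63, adjusted p = 0.218) or with the place in the repeat taken off (1.21, adjusted p = 0.0982). The chlorophyll synthesis gene CHLM, encoding magnesium-protoporphyrin IX methyltransferase, fell with a log2 fold change of -1.41 ± 0.22 (adjusted p = 0.000306; 0.0320 on pair averages). With the place taken off CHLM was at -0.85 (adjusted p = 0.00362) and did not pass with pair averages as well (adjusted p = 0.0694). NTRC, encoding a plastid NADPH-dependent thioredoxin reductase, changed by -0.80 ± 0.21 (adjusted p = 0.00879; 0.119 on pair averages) and was at -0.14 with the place taken off (adjusted p = 0.577), and the other antioxidant gene, AT3G52960, was at 0.78 ± 0.61 (adjusted p = 0.335). AT1G24360, encoding a ketoacyl-ACP reductase of fatty acid synthesis, rose by 1.68 ± 0.41 (adjusted p = 0.00656; 0.108 on pair averages) and by 0.93 with the place taken off (adjusted p = 0.0149), and FATB was at 0.10 ± 0.34 (adjusted p = 0.840). ETFQO, a gene of the sugar starvation list whose product feeds electrons from amino acid breakdown into respiration, changed by -1.13 ± 0.30 (adjusted p = 0.0101; 0.114 on pair averages) and was at -0.80 with the place taken off (adjusted p = 0.0301). On the deposited scale CHLM was at -1.95, NTRC at -1.31, AT1G24360 at 1.31 and ETFQO at -1.65, all past the threshold. Adjusted over the list alone, the calls in these lists were the same.

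In the remaining 3 lists under 5 measured genes, none passed over all probes without the replicate block. The carotenoid gene Z-ISO was at -3.55 ± 1.52 (adjusted p = 0.0811). Its probe was dim and had a value of 0 in 1 low CO2 sample, so its fold change and SE rest in part on the replaced 0. Its deposited values did not overlap, at 0.411 to 0.833 for normal and 0 to 0.161 for low CO2. The geranylgeranyl reductase gene AT1G74470 was at 0.22 ± 0.18 (adjusted p = 0.345). The protease gene SPPA was at -0.76 ± 0.30 (adjusted p = 0.0612) and passed when adjusted over the list alone, which holds 1 measured gene, and over all probes with the replicate block (adjusted p = 0.0122), but not on pair averages (0.236) or with pairs as a random block (0.161). The envelope transporter gene AT5G17630 was at 0.26 ± 0.20 (adjusted p = 0.321). For 14 lists no gene was measured by a probe of 1 gene, the 7 root and seed markers, carbonic anhydrases and starch enzymes among them, and these were not analysed here.

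Of 6 measured plastid ribosomal protein genes, 2 rose, 2 fell and 2 did not pass, both over all probes and adjusted over the list alone. Of the last 2, AT5G65220 had a value of 0 in 5 normal and all 6 low CO2 samples. Its fold change rests on replaced values and does not show an unchanged gene. AT3G13120 was higher by 0.50 ± 0.10 (adjusted p = 0.00179) and AT1G64510 by 0.74 ± 0.27 (adjusted p = 0.0462), but on the deposited scale these were at -0.00045 (adjusted p = 0.997) and 0.10 (adjusted p = 0.806). AT3G54210 changed by -0.77 ± 0.19 (adjusted p = 0.00593) and AT1G29070 by -0.65 ± 0.21 (adjusted p = 0.0240), where on the deposited scale these were at -1.14 and -1.13 (adjusted p = 0.000298 and 0.000766). None of the 4 passed on pair averages. AT1G64510 did not pass in 10 of the 12 fits that left out 1 sample or with the replicate block (adjusted p = 0.0953). AT1G29070 did not pass without low CO2 replicate 1 (adjusted p = 0.0504). The list as a whole did not differ from other probes (camera p = 0.855; 0.875 with an estimated correlation), its median being 0.02 and its mean -0.02. By fry, p was 0.757 for a common direction and 0.000221 for change in either direction. With the place in the repeat taken off, only AT1G29070 passed.

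A further 3 lists were drawn up after the probes present were known and before gene values were read. In the photosynthesis, pentatricopeptide repeat and mTERF lists, 10 of 20, 8 of 19 and 4 of 6 genes changed, against 42.4% of all probes. The photosynthesis list repeats PSAN, PSBW, PSBY, PSB27, LHB1B2, SBPASE and PRK from the lists above. Of 20 photosynthesis protein genes, 5 rose and 5 fell, against 3 and 7 on the deposited scale; AT5G58330, encoding NADP-dependent malate dehydrogenase, rose by 2.44 ± 0.42 (adjusted p = 0.000639), and LPA19, a photosystem II assembly gene, changed by -1.38 ± 0.12 (adjusted p = 8.67e-06). With the place taken off these were at 1.69 (adjusted p = 0.000360) and -0.65 (adjusted p = 0.00372), and with pair averages as well LPA19 did not pass (adjusted p = 0.0803). AT1G54500 changed by -0.90 ± 0.12 (adjusted p = 0.000105) and did not pass with the place taken off (-0.35, adjusted p = 0.0712). On pair averages 3 of the 20 passed. Of 19 pentatricopeptide repeat genes, 5 rose and 3 fell, against 3 and 7 on the deposited scale, and 7 passed on pair averages. AT3G26630 was at 1.61 ± 0.18 and AT4G14050 at -1.51 ± 0.16, and with the place taken off at 2.04 and -1.08, both past the threshold. Of 6 mTERF genes, which act on organelle transcripts, AT5G55580 rose and 3 fell, against 1 and 5 on the deposited scale, AT1G61990 by a log2 fold change of -1.66 ± 0.20 and AT1G62010 of -1.53 ± 0.27. On pair averages 3 of the 6 passed, as did 3 with the place taken off, where the median of the list was -0.09 against -0.68 before. Camera gave adjusted p of 0.932, 0.649 and 0.365 for the lists in this order, and 0.927, 0.711 and 0.711 with an estimated correlation. By fry, which does not compare a list with other genes, unadjusted p for a common direction was 0.0367, 0.126 and 0.000831, and for change in either direction 4.29e-13, 8.56e-15 and 0.000336.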

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

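The tests of the resemblance of samples and of the profile of single replicate pairs were chosen after the results were seen. In 4 of 90 sets of 6 values tested, a sample stood far from the others of its group, where chance gives about 4.5. For AT3G13150 the low CO2 replicate 3 had an intensity of 2.58 against 4.07 to 4.87 in the others, a gap of 0.780 of the range. For AT1G04420 the normal CO2 replicate 6 was at 1.17 against 1.62 to 2.07, a gap of 0.635. For LrgB the normal CO2 replicate 2 was at 0.0466 against 0.0768 to 0.212, a gap of 0.656, and the low CO2 replicate 4 at 0.0916 against 0.181 to 0.241, a gap of 0.743. Gaps were taken on normalized log2 values.

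For the 1457 changed probes, 1 of 100 splits of the 12 samples, the real one, called as many, and the highest of the others called 1 probe. This would exclude chance only if the 12 samples were independent, which the correlation of 0.567 estimated within adjacent pairs goes against. With adjacent pairs kept together only 10 splits count. The 31 other splits that part all same-numbered samples, which mix both groups on each side, called 0. For the 618 probes on pair averages, 1 of the 10 splits called as many and the highest other called 1. For either count 10 splits are too few for a share under 0.05. The mean correlation of deviations within pairs exceeded that between pairs by at least 0.270 in both groups. That of same-numbered samples across groups exceeded that of the other number of the pair by 0.121.

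Fold changes that repeat along the probe numbers were weighed against 3 technical explanations. Brightness is argued against, since the place in the repeat held 24.6% of the variance after the relation to brightness was removed and 24.4% before. A fault of a single pair of arrays is argued against too, because the lowest correlation of the profile between pairs was 0.856. An effect of the probe's place rather than its gene cannot be told apart from different sets of genes at different places: probes with the same annotation in bins of opposite sign differed by a median of 0.86 (22 annotations, 95% bootstrap interval 0.38 to 1.39), and the interval held the bound of 0.48 set for this test. The interval also held 0.965, the full gap in median log2 fold change between bins of opposite sign, measured without the compared probes. As all 22 annotations list several genes, the probes compared may stand for different genes. A response to low CO2 that differs between the sets of genes placed in each part stays open and untested.

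The lower deposited values of most probes at low CO2, with a median log2 difference of -0.53 ± 0.05 (SE) between array medians, may come from a few bright probes taking more of the total. Without the brightest 1% the difference was -0.275 ± 0.05, too near the bound of -0.266 set beforehand to decide. A lower signal of dim spots could also produce it. Among the 2862 probes without a 0 in any sample, the shift of the brightest 25% was 0.412 of that of the dimmest 25%. The bootstrap interval, 0.269 to 0.570, held the bound. It was drawn over probes as if they were independent, and the 577 probes with a 0 were not covered. A general fall in transcript levels at low CO2 stays open and was not tested.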

How the results depend on the processing

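The settings that take off the place in the repeat, leave out pairs of numbers or probes with a 0, or join pair averages with a replicate block were chosen after seeing the data. The count of 1457 changed probes moved by over 1.5 times under 3 settings: to 618 with pair averages, to 375 with pair averages and replicate block, and to 454 with the place taken off and pair averages, where 271 were higher and 183 lower. These use fewer samples in the test and also guard against noise shared within pairs. In the simulation pair averages cut the calls from 80 to 51 with independent noise and from 140 to 22 with shared noise, so both could lower the count. The replicate block gave 1578 and changed the call of AT1G64510 (adjusted p = 0.0953) among the 41 named genes. It also brought SPPA past the threshold (adjusted p = 0.0122), raised the changed genes of the pentatricopeptide list from 8 to 10 and of the mTERF list from 4 to 5, against 6 and 3 with pair averages and the block, and did not change the call of the ribosomal list test. Leaving out a replicate gave 1332 to 1425.

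The median of the plastid ribosomal list, 0.02 in the report, lay near 0 and its test passed under no setting (p of 0.539 to 0.981). It turned to -0.84 on the deposited scale, -0.30 with median scaling and -0.44 with 75th percentile scaling, to -0.011 without replicates 1 and 2 and -0.16 without replicates 5 and 6, and to -0.0073 with the place taken off, with or without pair averages. Leaving out a replicate gave -0.10 to 0.092. The cause was not tested. AT3G13120 reversed to -0.00045 on the deposited scale. Of 1188 values of named genes under alternatives, 1069 kept direction and side of the threshold, 118 lost the call and 1 reversed. Signal over background was not analysed here, and low signal, with a 0 in some sample for 577 probes, limits what fold changes show.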
